A study of Mus musculus with 8 samples.

How the data were processed

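RNA was measured in 8 libraries labelled as cultured mouse bone marrow stromal cells (BMSC, a name for the adherent mesenchymal cells that grow out of marrow and bone fragments). The cells came from Id1+/+ or Id1-/- mice harvested 6 weeks after transplantation with acute myeloid leukaemia driven by AE9a (AML1-ETO9a, a truncated fusion of RUNX1 and RUNX1T1) or by MLL-AF9 (a fusion of KMT2A and MLLT3). Each of the 4 groups of leukaemia model and genotype holds 2 samples. Total RNA was extracted with TRIzol, prepared with a TruSeq RNA kit and sequenced on an Illumina NovaSeq. The submitters' processing notes name fastp 0.22.0, HISAT2 2.2.1, featureCounts 2.0.1, DESeq2 1.32.0 and the mm10 genome, without saying which step each served. The strand setting and the annotation release are not stated, so overlapping genes on opposite strands may share reads.

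The authors deposited counts per gene name in separate tables for the 2 models, without normalization. The AE9a table has 55421 rows, of which 29761 are 0 in every column. The MLL-AF9 table has 15994 rows and none of the mitochondrially encoded names, of which the AE9a table has 37. The lowest row total in the MLL-AF9 table is 2. Of its names, 15879 also occur in the AE9a table. Of the AE9a rows, 27 carry a date in place of a name and 119 repeat a name; 6 rows repeat a name in the MLL-AF9 table.

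The columns of each group were compared gene by gene. In the MLL-AF9 table the replicates differed like separate libraries: over genes with at least 100 counts in both, the median chi-square of the difference was 2.187 for Id1+/+ and 1.707 for Id1-/-, against 0.455 for sampling noise alone. In the AE9a table, Id1+/+ replicate 1 equals replicate 2 plus 134 in 17957 of the 17958 genes with 2 or more counts in replicate 2, and is 0 in all 2231 genes with 1 count there. The exception is Id1, with 317 counts in replicate 1 and 383 in replicate 2. Id1-/- replicate 2 equals replicate 1 plus 17 in all 14187 genes with 10 or more counts in replicate 1. In the other 41234 genes it holds values from 0 to 9, with a Spearman rho of -0.656 across the 9868 genes above 0 in either column. The cause of this relation is not known. AE9a replicates were therefore counted as 1 library per genotype, using the columns without the added constant (Id1+/+ replicate 2 and Id1-/- replicate 1). The other deposited AE9a columns hold other values than counts: a constant added over most genes with counts, and 0 or other low values elsewhere. They served only in 1 alternative. The tests planned for AE9a alone were not run, since 1 library per genotype leaves no replicate spread.

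Library totals were 21480068 and 22510346 counts for MLL-AF9 Id1+/+, 18727623 and 17864812 for MLL-AF9 Id1-/-, and 20967896 and 18126803 for the AE9a Id1+/+ and Id1-/- columns used. A count of 0 was treated as at most 3 counts, over all libraries of the group. Intervals on AE9a ratios are 95% exact binomial intervals for a pair of counts. They and the floors cover counting error only, because reads without molecular identifiers are not independent molecules and a lone library says nothing about variation between animals.

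For MLL-AF9, genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood F tests (two-sided, 2 libraries per genotype), with Benjamini-Hochberg (BH) adjustment over all genes tested and a threshold of 0.05, in R 4.3.3. Levels are given as TMM-scaled counts relative to library size (CPM) with the SD of 2 libraries. Fold changes are log2 of Id1-/- over Id1+/+ from the fit, with the default prior count of edgeR. On simulated counts with the dispersion of these libraries, the fit found 62.7% of genes changed 1.5-fold, 83.6% of those changed 2-fold and all 66 changed 4-fold, with 6 false calls among 170. With no gene changed it made 0 calls. The simulation changed few of its 14137 genes, with random signs, and drew counts from the model that the test assumes. In the data 27.8% of genes were called, 61.8% of them higher, so the simulated false calls do not measure those among the real calls. For AE9a, genes with at least 10 counts over both columns used were kept. Their log2 ratio was computed after TMM scaling, with a prior count of 2. Genes with a mean of at least 1 CPM and a ratio of at least 2-fold were counted. Where counts are few, the folds of the 2 models are therefore shrunk differently. A joint edgeR fit of the 6 usable libraries by model and genotype gave the interaction of model and genotype, and the genes called in both models. It assumes that each lone AE9a library varies like the MLL-AF9 libraries. The overlap of calls was tested with a one-sided Fisher exact test within that joint fit, where separate fits had been planned.

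Before the data were examined, 32 gene lists were fixed, covering the Id family, angiopoietin-like genes, niche factors, stromal lineages, matrix, cell cycle, signalling responses, metabolism, blood and other cell type markers, sex-linked transcripts and genes near Id1. The 31 lists with at least 3 genes tested were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, BH over the lists. Members were counted at the BH threshold over all genes and adjusted over the list alone. AE9a list medians were set against 10000 random lists of the same size and abundance. Genes were named by a rule fixed at the same time: Id1 and Angptl7; up to 10 higher and 10 lower called genes with the largest fold among those with at least 20 normalized counts in the higher group and no overlap of the groups, leaving out predicted genes, pseudogenes and antigen receptor segments; up to 3 members of each list with the smallest adjusted p; and up to 5 genes each called higher in both models, lower in both, or with an interaction. For AE9a alone the same number of genes with the largest ratios was taken. Outside this rule, Angpt2, Id4, Col3a1, Col6a2, Atf4, Pcna, Mpeg1, Cd68, Tyrobp and the 5 most abundant genes were chosen after their values were seen. So were Tnf and Cxcl2. Positions are from GENCODE M21 (GRCm38), matched by symbol for 98.6% of the genes tested.

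Alternatives fixed before the data were examined were DESeq2 size factors, no filter, a filter at 50 normalized counts, DESeq2 1.42.0, limma-voom, a 2-fold minimum, a replicate block, the joint fit and leaving out each library. Library totals without TMM, the mean of both AE9a columns, the Id1 count that the other AE9a Id1+/+ column implies, and list counts under each alternative were added after the data were seen.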

Results

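Bone marrow stromal cell cultures were compared between Id1+/+ and Id1-/- mice that had carried acute myeloid leukaemia for 6 weeks. Id1 encodes a helix-loop-helix protein that blocks DNA binding by basic helix-loop-helix transcription factors. The design addresses what Id1 does for leukaemia-initiating cells from the surrounding tissue, and the study title names the secreted protein ANGPTL7. RNA was counted per gene in 2 libraries for each genotype and leukaemia model (MLL-AF9 or AE9a), at 17864812 to 22510346 counts per MLL-AF9 library. In AE9a, the 2 columns of a genotype differ by a fixed number of counts over most genes with counts (134 in 17957 genes for Id1+/+, 17 in 14187 genes for Id1-/-), so each genotype was counted as 1 library, of 20967896 counts for Id1+/+ and 18126803 for Id1-/-. Tests between genotypes therefore rest on the MLL-AF9 libraries (n = 2 per genotype), and AE9a values are single measurements with intervals for counting error. The labels used here number the replicates without naming the animals. The MLL-AF9 p-values thus measure genotype against the spread between libraries, which need not be the spread between mice.

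The MLL-AF9 libraries answer which genes differ in stromal cultures without Id1. Genes of the extracellular matrix were higher in Id1-/- cultures: Col1a1 rose from 203 ± 31.1 to 1290 ± 112 CPM (mean ± SD, n = 2 libraries) and Col1a2, its partner chain in type I collagen, from 325 ± 20.9 to 1800 ± 83.4. Among 25 interferon-stimulated genes 15 were lower and 3 higher, and 8 of 10 neutrophil markers were lower, list calls that were lost with an estimated correlation (adjusted p = 0.288 and 0.29). Ccl2, which recruits monocytes, fell from 188 ± 15.6 to 65 ± 2.45 CPM. Cxcl12, the chemokine that retains haematopoietic cells in marrow, fell from 78.8 ± 8.81 to 32.4 ± 0.29 CPM, and Spp1 (osteopontin) from 10000 ± 481 to 5240 ± 137. The most abundant transcripts of the Id1+/+ cultures were Ctsb, Gpnmb, Psap, Fth1 and Lyz2. Of the 50 most abundant genes of Id1+/+ cultures, 36 were lower in Id1-/-, 0 were higher and 14 were not called. Their median log2 fold was -0.32, and choosing genes by their Id1+/+ level favours those that are high there. Those 50 include Lyz2, Mpeg1, Cd68 and Tyrobp of the macrophage list, so the values describe cultures of mixed cell types. Macrophage marker transcripts made up 3.21% and 3% of all counts in Id1+/+ and 2.89% and 2.83% in Id1-/-. Matrix transcripts made up 0.267% and 0.302% in Id1+/+ and 0.998% and 1.08% in Id1-/-. Mesenchymal marker transcripts made up 0.201% and 0.207% in Id1+/+ and 0.227% and 0.22% in Id1-/-. Macrophage marker transcripts thus outnumbered those of both stromal lists in every MLL-AF9 library. Shares of listed transcripts are not shares of cells.

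Id1 itself (ENSMUSG00000042745.9, chromosome 2, 152736251 to 152737410, 1 exon) fell from 31.7 ± 4.07 to 11.8 ± 0.323 CPM, a log2 fold change of -1.43 (SE 0.12, edgeR quasi-likelihood BH-adjusted p = 4.23e-07). Reads on the gene remained in both knockout libraries, with 226 and 222 counts against 706 and 632. Angptl7 (ENSMUSG00000028989.3, chromosome 4, 148495183 to 148500460, inside Mtor on the other strand with no exon overlap) fell from 71.5 ± 5.66 to 34.3 ± 0.264 CPM, a log2 fold change of -1.06 (SE 0.09, adjusted p = 4.59e-07). Angptl7 is named in the study title, so its direction here is not counted as independent evidence. Of the 4 Id genes, Id2 also fell (log2 -0.54), Id3 rose (0.70) and Id4 was not called (0.43). Adjusted over the list alone 2 were higher and 2 lower, and as a list they were not called (camera adjusted p = 0.25). Among 7 angiopoietin-like and angiopoietin genes, Angptl7, Angptl2 (-0.44) and Angpt2 (-0.74) fell and Angpt4 rose (0.93), though without Id1-/- replicate 1 Angpt4 had a log2 fold of 0.77 and no call. Over that list alone 2 were higher and 3 lower, with a camera adjusted p of 0.12.

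**Figure D1:**
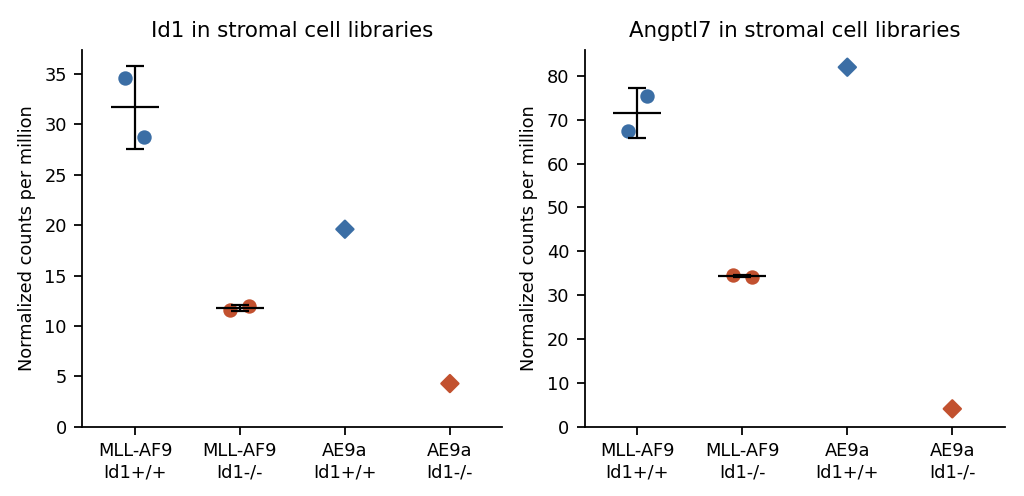
Normalized counts (CPM) of Id1 (left) and Angptl7 (right) in each library used, with the mean and SD of 2 libraries for MLL-AF9 (circles, bars) and 1 library per genotype for AE9a (diamonds). Both genes lie lower in Id1-/- in both models, at 34.3 against 71.5 for Angptl7 in MLL-AF9 and 4.07 against 82 in AE9a; the AE9a Id1+/+ point for Id1 rests on 383 counts, where the other column implies 183.

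Matrix genes moved together. Of 25 collagens and matrix proteins tested, 24 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold of 1.57 and called members between 0.97 and 2.67 (camera adjusted p = 1.43e-109; adjusted p = 0.288 with an estimated correlation). Col6a2, a chain of microfibrillar collagen, rose from 42.6 ± 0.862 to 212 ± 25 CPM (log2 2.31, SE 0.10, adjusted p = 1.58e-10), and Col1a1 and Col1a2 by 2.67 and 2.47. Of 18 matrix proteases and inhibitors, 13 rose and 4 fell, 13 and 4 over the list alone (median 0.97, camera adjusted p = 2.97e-11; adjusted p = 0.288 with an estimated correlation). Timp3, an inhibitor bound to the matrix, rose by 1.95 on the log2 scale, the gelatinase Mmp2 by 1.70 and the procollagen protease Adamts2 by 1.84. In the osteoblast list 8 of 12 rose and 1 fell, 8 and 1 over the list alone (median 1.40, camera adjusted p = 2.38e-11; adjusted p = 0.288 with an estimated correlation). There Alpl, the mineralizing phosphatase, rose from 14.6 ± 0.399 to 67.2 ± 0.416 CPM, Sparc rose from 481 ± 1.3 to 1330 ± 80.2, and the member that fell was Spp1 (-0.93). Smooth muscle and pericyte markers rose in 7 of 8 cases, 7 also over the list alone (median 1.05, camera adjusted p = 8.41e-08; adjusted p = 0.29 with an estimated correlation). Acta2 rose by 1.14, Cnn1 by 1.47 and Mylk by 1.13, all contractile proteins or their kinase.

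The Wnt and Notch, TGF-beta and BMP, amino acid stress and cell cycle lists were also called higher by camera with the preset correlation. In the Wnt and Notch list 13 of 16 genes rose and 1 fell, 13 and 2 over the list alone (median 1.26, camera adjusted p = 9.99e-11; adjusted p = 0.29 with an estimated correlation). Ccn5 rose from 15.5 ± 1.35 to 84.3 ± 4.52 CPM, and the secreted Wnt modulators Dkk3 and Sfrp1 by 1.97 and 1.65 on the log2 scale. In the TGF-beta and BMP list 12 of 18 rose and 2 fell, 12 and 3 over the list alone (median 0.61, camera adjusted p = 2.22e-07; adjusted p = 0.29 with an estimated correlation). Its members with the smallest adjusted p were Acta2, the ligand Tgfb3 (1.43) and Ccn1 (0.90). Of that list 0 were lower without Id1+/+ or Id1-/- replicate 1 and 1 without either replicate 2. Of 18 genes of the amino acid stress response, 13 rose and 0 fell, 14 over the list alone (median 0.85, camera adjusted p = 9.49e-17; adjusted p = 0.288 with an estimated correlation). The amino acid transporter Slc7a5 rose from 12.3 ± 0.114 to 50.7 ± 1.43 CPM, and the serine synthesis enzymes Phgdh and Psat1 by 1.99 and 1.61, while Atf4, the transcription factor of that response, had a log2 fold of -0.08 and was not called. Cell cycle genes rose in 25 of 30 cases and 1 fell, 27 and 2 over the list alone (median 0.72, camera adjusted p = 3.37e-07; adjusted p = 0.533 with an estimated correlation). Top2a rose from 21.7 ± 2.08 to 53.9 ± 11.9 CPM and Mki67 from 14.8 ± 2.87 to 33.5 ± 5.06, and Pcna fell by 0.56 on the log2 scale. This list was higher in Id1-/- replicate 1 than in replicate 2 (median log2 0.43), and 10 members were higher and 1 lower without replicate 1, with a median of 0.45 and a camera adjusted p of 0.000341.

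Of 25 interferon-stimulated genes 15 fell and 3 rose, 16 and 3 over the list alone (median -0.57, camera adjusted p = 4.61e-07; adjusted p = 0.288 with an estimated correlation). The transcription factor Irf7 fell from 61.5 ± 0.688 to 35.6 ± 0.696 CPM, and Ifit1 and Ifit3, which bind viral RNA or its sensors, by 1.21 and 1.19 on the log2 scale. Without Id1-/- replicate 1, 11 were lower and 0 higher. Neutrophil markers fell in 8 of 10 cases, 8 over the list alone, and 0 rose (median -0.82, camera adjusted p = 1.39e-08; adjusted p = 0.29 with an estimated correlation), with Chil3 at -1.33 and the calprotectin genes S100a9 and S100a8 at -1.12 and -0.85. Of 19 inflammatory cytokines and chemokines 9 fell and 3 rose, 11 and 5 over the list alone. The median was -0.45, the mean 0.06 (camera lower, adjusted p = 0.000657; adjusted p = 0.327 with an estimated correlation). Ccl2 (-1.53), Ccl9 (-0.88) and Saa3 (-1.02) had the smallest adjusted p. Members that rose include Tnf (log2 2.42) and Cxcl2 (2.79), both far higher in Id1-/- replicate 1 than in replicate 2. Tnf was at 180 and 53.8 CPM in those libraries, against a mean of 21.8 in Id1+/+. Cxcl2 was at 51.2 and 13 CPM, against 4.66. Without Id1-/- replicate 2 the camera p of that list was 0.928, and 5 members were lower without Id1+/+ replicate 1 or with DESeq2 and 4 with library totals. Myeloid progenitor and blast markers fell in 8 of 17 cases and 1 rose, 9 and 1 over the list alone (median -0.31, camera adjusted p = 0.00167; adjusted p = 0.29 with an estimated correlation). The granule proteases Elane (15.4 ± 2.18 to 4.97 ± 1.17 CPM) and Ctsg (-1.66) and the peroxidase Mpo (-1.29) fell. Of that list 5 members were lower with library totals and without Id1+/+ replicate 1, Id1-/- replicate 1 or Id1-/- replicate 2. The 6 B lymphocyte markers tested include 4 that rose, 4 over the list alone, and 0 that fell (median 0.98, camera adjusted p = 1.25e-05; adjusted p = 0.288 with an estimated correlation), with the antibody light chain Igkc at 1.96 and Ighm at 0.95. Erythroid markers rose in 3 of 4 cases, 3 over the list alone (camera adjusted p = 0.0227; adjusted p = 0.533 with an estimated correlation). This list was higher in Id1-/- replicate 1 than in replicate 2 (median log2 0.55), and it lost its call with library totals (0.0583), no filter (0.231), without Id1+/+ replicate 1 (0.13, 1 member higher) and without Id1+/+ replicate 2 (0.165); without Id1-/- replicate 1, 1 member was higher.

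**Figure D2:**
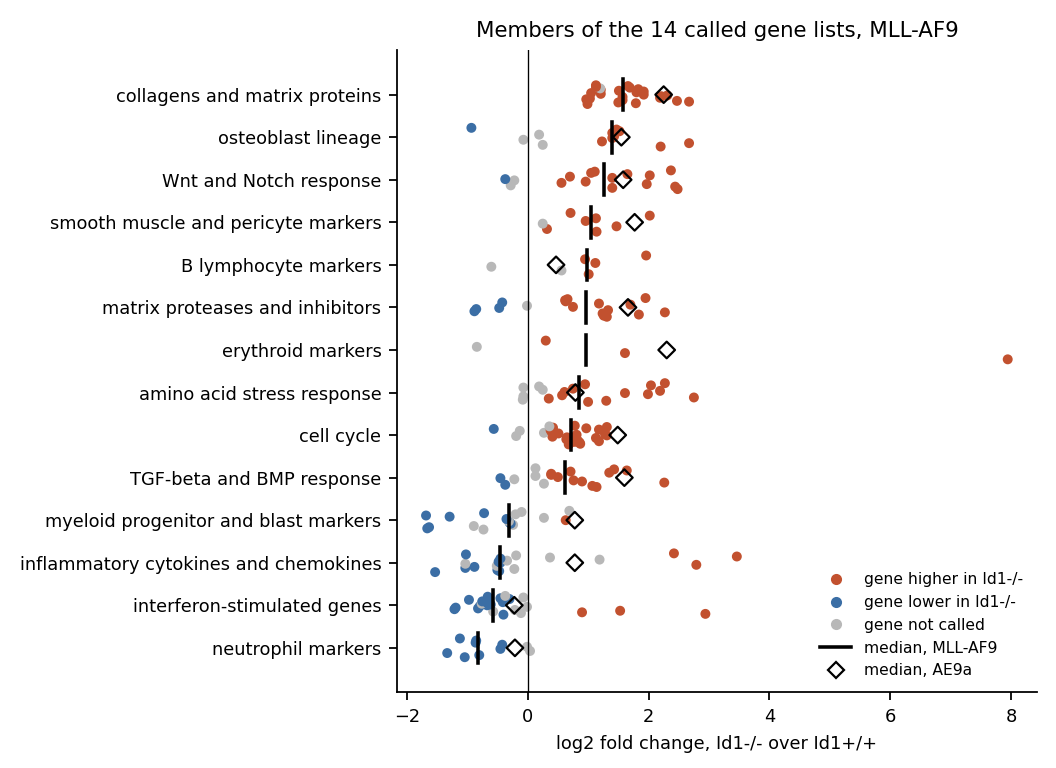
Log2 fold change of each tested member of the 14 called gene lists in MLL-AF9 (dots, coloured by call), with the MLL-AF9 median (bar) and the AE9a median (open diamond). All called matrix genes lie between 0.97 and 2.67, while the interferon list has 15 members below 0 that were called and 3 above.

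By camera 14 of 31 lists were called, 10 higher and 4 lower; with an estimated correlation 0 were called, and 5 had an unadjusted p under 0.05. The other 17 were not called with the preset correlation. Among the called lists, the estimated correlation was below the preset 0.01 for interferon (-0.0383), amino acid stress (-0.00369), myeloid progenitor (-0.0281) and B lymphocyte genes (-0.173). For those lists a larger correlation between genes cannot be why the call was lost. The estimate ran from 0.11 to 0.91 for the remaining called lists. Mesenchymal stromal cell markers had 9 of 18 higher and 2 lower, 9 and 4 over the list alone (adjusted p = 0.0617; 0.0361 without Id1-/- replicate 1 and 0.0498 with library totals), with Prrx1 at 1.42, Pdgfrb at 1.07 and Cxcl12 at -1.28. Niche factors had 4 of 16 higher and 3 lower, 5 and 4 over the list alone (adjusted p = 0.25), and Ptn, a growth factor that binds heparin, rose from 1.12 ± 0.357 to 17.9 ± 0.00727 CPM. Chondrocyte and tendon genes had 4 of 7 higher and 1 lower, the same numbers over the list alone (adjusted p = 0.0512, and 0.0493 with DESeq2 size factors), led by Col2a1 (1.78); 2 were higher without Id1+/+ replicate 2 or without either Id1-/- replicate. Adipocyte genes had 1 of 10 higher and 2 lower, 1 and 3 over the list alone, with a median of -0.16 and a mean of 0.08 (camera lower, adjusted p = 0.154, and 0.0493 without Id1+/+ replicate 2), with Plin2 at -0.47; 1 was lower without Id1+/+ replicate 1, Id1-/- replicate 1 or Id1-/- replicate 2 and with library totals, and 4 with DESeq2. Macrophage markers had 5 of 20 higher and 8 lower, 5 and 9 over the list alone, with a median of -0.14 and a mean of 0.08 (adjusted p = 0.389). Of these 5 were lower without Id1+/+ or Id1-/- replicate 1, 4 without Id1-/- replicate 2 and 4 with library totals. Within it the scavenger receptor Marco (1.86) and Mrc1 (0.68) rose and Fcer1g (-0.72) fell. Osteoclast markers had 3 of 8 higher and 2 lower, 3 and 2 over the list alone (adjusted p = 0.813). The CDK inhibitor and p53 list had 6 of 18 higher and 3 lower, 8 and 3 over the list alone (adjusted p = 0.473), with Cdkn2a, the Ink4a and Arf locus, at 1.66. Of these 3 were higher with DESeq2 and without Id1+/+ replicate 1 or either Id1-/- replicate, and 1 lower without Id1-/- replicate 1.

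Glycolysis and hypoxia genes had 3 of 23 higher and 7 lower, 3 and 8 over the list alone (adjusted p = 0.142), with P4ha2, a collagen prolyl hydroxylase, at 1.30. Of these 1 was higher and 3 lower without either Id1-/- replicate, and 1 was higher without Id1+/+ replicate 1; library totals gave 4 lower. Angiogenesis regulators had 4 of 14 higher and 3 lower, 4 and 3 over the list alone (adjusted p = 0.133), and 1 was lower without Id1+/+ replicate 1. Immediate early and heat shock genes had 6 of 15 higher and 0 lower, 7 and 1 over the list alone (adjusted p = 0.0972), 3 higher with DESeq2; without Id1-/- replicate 2 the list was called (0.000345). Egr1 there rose from 26 ± 2.7 to 114 ± 53.4 CPM, with a log2 fold of 2.14 that was 1.55 without Id1-/- replicate 1. Markers of mast cells, basophils and megakaryocytes had 1 of 5 higher and 1 lower, 1 and 1 over the list alone (median 0.28, camera lower, adjusted p = 0.336), with Pf4 at -1.44; 2 were higher without Id1+/+ replicate 2 or Id1-/- replicate 1. Of the muscle, nerve and glia markers, Ncam1 rose (1.25), also over the list alone, and as a list they were not called (adjusted p = 0.203). None of 3 T and NK lymphocyte markers (adjusted p = 0.813) and none of 5 endothelial markers (adjusted p = 0.868) was called by edgeR, DESeq2 or limma-voom, or by edgeR over the list alone. The smallest unadjusted edgeR p was 0.648 for Ccl5 and 0.05 for Erg, which was called with library totals (adjusted p = 0.0351, 0.0351 to 0.384 over the alternatives). Of 17 genes near Id1 on chromosome 2, 4 were higher and 3 lower, 4 and 4 over the list alone (median 0.05, camera lower, adjusted p = 0.684), and 2 were higher without Id1+/+ replicate 2 and 1 without either Id1-/- replicate. Both sex-linked transcripts tested were higher, also over the list alone: Xist, expressed from the inactive X, from 205 ± 38 to 294 ± 26.2 CPM (adjusted p = 0.00187, 0.0589 with DESeq2, 3.2e-13 to 0.0589 over the alternatives), and the Y-linked Eif2s3y, with 0 counts in both Id1+/+ libraries and 42 and 9 in Id1-/-.

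The genes with the largest fold were often unequal between the Id1-/- libraries. Mycn, a transcription factor of the Myc family, had 0 counts in both Id1+/+ libraries and 1146 and 270 in Id1-/- replicates 1 and 2, at least 517-fold higher against a floor of 3 counts over the group (adjusted p = 1.51e-06). The sodium pump regulator Fxyd2 had 0 counts against 658 and 155, at least 297-fold higher. The protease inhibitor Spink5 had 0 counts against 450 and 69, at least 189-fold, and the interferon-induced Ifi44l 0 counts against 54 and 15, at least 25.2-fold. Car2, a carbonic anhydrase abundant in red cells and osteoclasts, was at 0.343 and 0.228 CPM in Id1+/+ and at 113 and 28.9 in Id1-/-. Ranbp3l (log2 7.16), the tight junction gene Cldn11 (6.09) and the neurturin receptor Gfra2 (5.38) rose from 3 counts or fewer over both Id1+/+ libraries. Ifi202b, an interferon-inducible member of the Ifi200 family on chromosome 1 (173962568 to 173982744), had 1 and 0 counts in Id1+/+ and 71 and 59 in Id1-/- (log2 6.84, SE 0.63, adjusted p = 7.23e-07). Depth limits these folds, since they rest on at most 12 Id1+/+ counts.

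**Figure D3:**
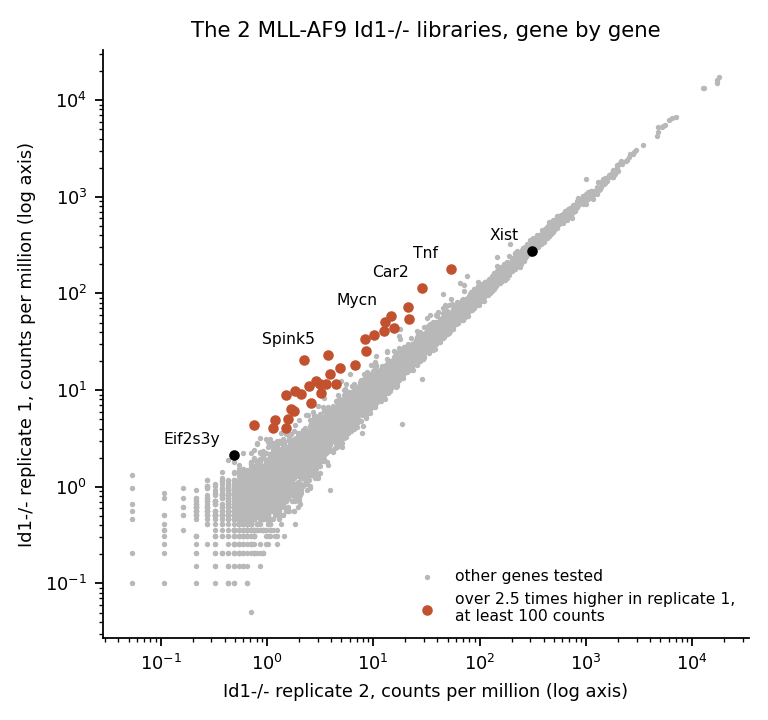
Normalized counts (CPM) of each tested gene in MLL-AF9 Id1-/- replicate 1 against replicate 2, both axes logarithmic, with 33 genes over 2.5 times higher in replicate 1 at 100 or more counts in red and Eif2s3y and Xist in black. Mycn lies at 58.6 against 14.6 and Car2 at 113 against 28.9, while most genes lie on the diagonal.

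Among the lower genes, Csta2, a cysteine protease inhibitor of the stefin family, fell from 2.32 ± 0.318 to 0.0782 ± 0.0341 CPM (log2 -4.77, SE 0.57, adjusted p = 1.19e-05). The ubiquitin ligase Rnf183 (-2.57), the muscle protein Klhl41 (-1.94), the transmembrane collagen Col23a1 (-1.91) and U90926 (-1.88) also fell. Sfrp5 (-2.11), Itga8 (-1.77), Ifit1bl1 (-1.73), Tfpi2 (-1.70) and Ms4a3 (-1.68) were called at 15 to 35 counts per Id1+/+ library and depend on single libraries and on the test. Without Id1+/+ replicate 1 none of these 5 was called (adjusted p = 0.299, 0.0527, 0.258, 0.0994 and 0.316 in that order). With DESeq2 and all libraries none was called either (0.0722, 0.068, 0.122, 0.053 and 0.0922). Over the fits that leave out 1 library their adjusted p ran from 0.0192 to 0.299, 0.0272 to 0.153, 0.0546 to 0.258, 0.0155 to 0.135 and 0.0226 to 0.316.

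Across the transcriptome, 14137 genes were tested in MLL-AF9 and 3936 (27.8%) were called by edgeR, 2434 higher and 1502 lower in Id1-/-, with a biological coefficient of variation of 7.48%. At least a 2-fold change was seen in 1085 of the higher and 68 of the lower genes. Called higher genes were less abundant (median 12.4 CPM) than called lower genes (71.7 CPM). Higher genes made up 61.8% of calls with TMM and 84% with library totals, which shift the median of all genes by 0.111 on the log2 scale and leave 598 lower. Without Id1+/+ replicate 1 the counts were 1555 higher and 764 lower, 1604 and 621 without Id1-/- replicate 1, and without Id1-/- replicate 2 1722 and 755.

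In AE9a, the other leukaemia model, the same direction was seen for Id1 and Angptl7. Angptl7 had 1605 counts in Id1+/+ and 79 in Id1-/- (82 and 4.07 CPM), a log2 ratio of -4.30 (counting interval -4.68 to -4.01). Id1 had 383 and 83 counts, a ratio of -2.17 (-2.55 to -1.85). Its Id1+/+ count is uncertain beyond that interval: Id1 is the exception to the relation of the columns, and the other column (317) implies 183 counts and a ratio of -1.11, an alternative chosen after the data were seen. All 24 matrix genes measured had ratios above 0, between 0.39 and 2.99, with a median of 2.25, at percentile 100 of 10000 random lists. Col1a1 went from 62.2 to 349 CPM and Col3a1 from 3.27 to 21.2. Ratios were above 0 for 28 of 30 cell cycle genes (median 1.49), for all 19 TGF-beta and BMP genes (1.6), for 15 of 16 Wnt and Notch genes (1.58), for 16 of 18 mesenchymal markers (1.73) and for all 10 smooth muscle markers (1.77). Markers of other cell types were also above 0, with 9 of 10 erythroid (2.3, percentile 100) and 7 of 10 endothelial markers (1.28, percentile 99.4). Interferon-stimulated genes had 18 of 25 ratios below 0 (median -0.22, percentile 0.33 of random lists), and neutrophil markers 6 of 9 (-0.21, percentile 15.4, within the random range of -0.39 to 0.71). Inflammatory genes had a median of 0.78 (percentile 100, random range -0.23 to 0.36), with 12 of 20 above 0. Myeloid progenitor markers had a median of 0.78 (percentile 99.2, random range -0.22 to 0.57), with 14 of 16 above 0. Both lists were called lower in MLL-AF9, so their AE9a medians went the opposite way. Lists not called in MLL-AF9 also reached percentile 100, such as niche factors (1.14) and CDK inhibitors and p53 targets (0.49). Matrix transcripts were 0.189% of counts in Id1+/+ and 0.815% in Id1-/-, macrophage markers 3.68% and 3.21%, and mitochondrially encoded transcripts 3.8% and 5.46%.

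Among genes absent from the AE9a Id1+/+ library, Ifi202b had 312 counts in Id1-/- (at least 105-fold), the secreted neuronal guidance protein Reln 38 (at least 12.8-fold), the matrix glycoprotein Sparcl1 37 (at least 12.5-fold), Cap2 31 (at least 10.4-fold) and Tspan11 21 (at least 7.04-fold). Osr1, a transcription factor of mesenchyme, went from 1 to 49 counts (log2 4.10, interval 3.08 to 10.96). Next to Angptl7, the lowest ratios were those of Fam71a (48 to 2 counts, -3.63, interval -7.66 to -2.64), the lipopolysaccharide carrier Lbp (32 to 3, -2.76, -5.75 to -1.73), Kcnk7 (50 to 6, -2.69) and Orm1 (65 to 11, -2.35), an acute phase protein. Of 12735 genes with a mean of at least 1 CPM, 1473 were at least 2-fold higher and 193 at least 2-fold lower in Id1-/-; this size rule involves no test, and AE9a has no replicates of its own. They depend on the settings: no filter gave 3659 and 915, library totals 102 lower and the filter at 50 counts 110 lower.

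The pair of models was compared to see which differences recur. Of the 2130 genes called higher in MLL-AF9 and measured in AE9a, 1724 (80.9%) had an AE9a ratio above 1, with a median log2 ratio of 0.74 against -0.01 to 0.03 in 1000 random lists of like abundance. Of 1450 called lower, 1202 (82.9%) were below 1, with a median of -0.29 against -0.10 to -0.06. Among genes not called, 46.6% were above 1. Across the 12360 genes in both, which are not independent replicates, fold changes correlated with a Pearson r of 0.59 and a Spearman rho of 0.46. In the joint edgeR fit of 15111 genes, which lends AE9a the spread of the MLL-AF9 libraries, 1841 genes were called higher and 2321 lower in AE9a Id1-/-, a balance opposite to that of the 2-fold counts. Of these, 1083 were called higher in both models (292 if the calls were independent, odds ratio 13, with a p below what the software holds) and 738 lower in both (228, odds ratio 7.49, one-sided Fisher exact p = 1.27e-243). The genes in this overlap are not independent, and both sets of calls come from 1 fit. Its Fisher values say nothing on variation between animals. Joint AE9a values of well-counted genes such as Ccl2 (1.82 against 1.92) and Col1a2 (2.37 against 2.47) lay below the separate ratios. S100a9, with few Id1+/+ counts, went the other way (3.67 against 3.46). With library totals in place of TMM, the joint fit gave 129 genes lower and 1618 higher in both models. The number of lower genes thus depends on the scaling. Whether joint TMM adds lower calls over TMM within each model was not tested. Genes higher in both with the smallest adjusted p were Col1a2 (log2 2.47 in MLL-AF9, 2.37 in AE9a), Timp3 (1.94 and 2.31), Col5a2, Lox, which cross-links collagen, and Sparc. The lower genes were Cxcl12 (-1.29 and -1.92), Angptl7 (-1.07 and -4.43), Id1 (-1.43 and -2.29, or -1.22 in AE9a with the implied count, adjusted p = 0.000839), Spp1 (-0.94 and -1.07) and Saa3 (-1.03 and -1.35).

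The effect of genotype differed between the models for 1556 genes in the same fit (interaction, BH-adjusted, the lone AE9a libraries assumed to vary like the MLL-AF9 ones). Ccl2 was lower in MLL-AF9 Id1-/- (-1.54) and higher in AE9a Id1-/- (1.82), a difference of 3.36 (SE 0.17, adjusted p = 3.43e-08), and Ccl7, another monocyte chemokine, went from -1.04 to 2.12 (difference 3.16). The BMP antagonist Grem1 was at -0.23 in MLL-AF9 and 2.32 in AE9a, and Ctse, a cathepsin, at -0.27 and 2.36, although its MLL-AF9 call was lost without Id1+/+ replicate 1 or either Id1-/- replicate (adjusted p = 0.105, 0.108 and 0.13). Angptl7 fell further in AE9a (difference -3.36, SE 0.20, adjusted p = 9e-08). For Id1 the difference was -0.86 (SE 0.25, adjusted p = 0.0376), and 0.21 (SE 0.26, adjusted p = 0.678) with the implied count. Of these genes, 139 were called in both models with opposite signs. The interaction count was 776 with DESeq2 and 894 without MLL-AF9 Id1-/- replicate 2, and genes lower in both numbered 129 with library totals, 415 without Id1+/+ replicate 1, 295 without Id1-/- replicate 1 and 395 without Id1-/- replicate 2, and those higher in both 617 with DESeq2.

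**Figure D4:**
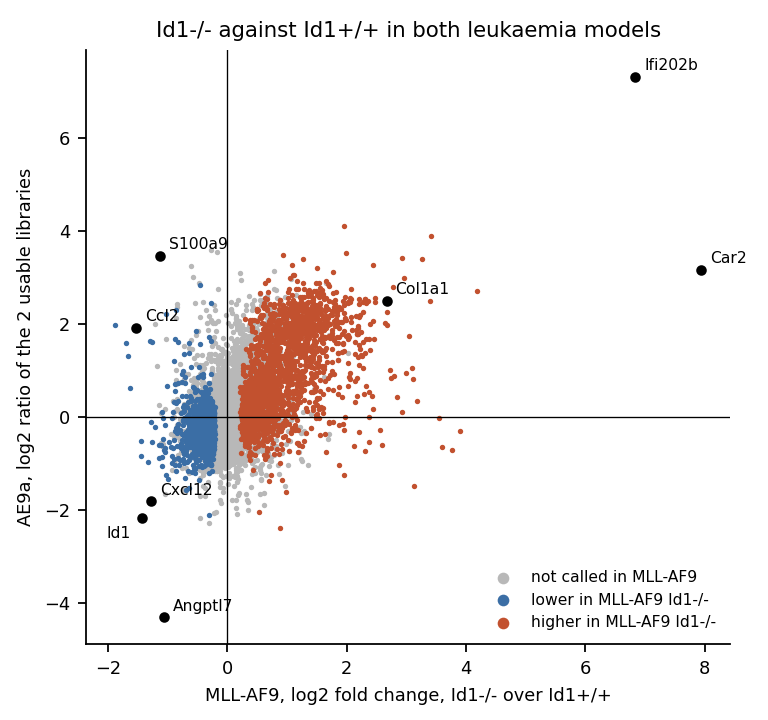
Log2 fold change between Id1-/- and Id1+/+ in MLL-AF9 (horizontal, 2 libraries per genotype) against the log2 ratio of the 2 AE9a libraries used (vertical) for 12360 genes, coloured by MLL-AF9 call. Angptl7 lies at -1.06 and -4.30, Col1a1 at 2.67 and 2.49, and Ccl2 at -1.53 and 1.92.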

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

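The tests in this part were chosen after the results were seen, except the interaction test. The comparison of genes beside Ifi202b was set before its own result was seen, but after Ifi202b had stood out. The pattern each test addresses was found in the same libraries.

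Among the named genes, 9 were called in both models with opposite signs and passed the interaction threshold, all in the joint edgeR fit. The interaction is the difference of the same effects in that fit, so it adds no independent support to the opposite signs. Ccl2, Ccl7 and Ctse had also been named for their small interaction p. The monocyte chemokine Ccl2 fell in MLL-AF9 (log2 -1.54) and rose in AE9a (1.82), a difference of 3.36 (SE 0.17, adjusted p = 3.43e-08), and Ccl7 (-1.04 and 2.12, difference 3.16, SE 0.22, adjusted p = 8.65e-07) did the same. Ccl9 went from -0.89 to 0.62 (difference 1.51, SE 0.16, adjusted p = 4.86e-05). The neutrophil marker S100a9 (-1.12 and 3.67, difference 4.8, SE 0.46, adjusted p = 2.1e-05) and Mpo (-1.3 and 1.6, difference 2.91, SE 0.43, adjusted p = 0.000846) also turned. So did U90926 (-1.89 and 2.09, difference 3.98, SE 0.64, adjusted p = 0.00137) and Tfpi2 (-1.71 and 1.56, difference 3.26, SE 0.64, adjusted p = 0.00507). S100a9 had 7 AE9a Id1+/+ counts, and the other calprotectin gene, S100a8, did not turn (-0.85 and -0.31, not called in AE9a or by interaction). Elane (-1.64 and 0.57) and Ctsg (-1.66 and 1.35) differed by interaction but were not called in AE9a. The transferrin receptor Tfrc was higher in MLL-AF9 (0.3) and lower in AE9a (-0.68), a difference of -0.98 (SE 0.15, adjusted p = 0.000991), but its MLL-AF9 call was lost without Id1+/+ replicate 1 (adjusted p = 0.112) and without Id1-/- replicate 1 (0.301). Ctse (-0.27 and 2.36, difference 2.64, SE 0.19, adjusted p = 1.04e-06) lost its MLL-AF9 call with DESeq2 (0.0706), with library totals (0.203) and without Id1+/+ replicate 1 (0.105), Id1-/- replicate 1 (0.108) or Id1-/- replicate 2 (0.13). Without Id1-/- replicate 2 Tfpi2 lost its MLL-AF9 call (0.0978), and with DESeq2 Tfpi2 lost both calls (0.0625 and 0.218) and Mpo (0.0707) and U90926 (0.104) their AE9a calls. In AE9a the level rests on 1 library per genotype, so a difference between animals or cultures and a difference between leukaemias were not separated.

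Some genes were far higher in MLL-AF9 Id1-/- replicate 1 than in replicate 2: 33 of 11369 genes lay over 2.5 times higher, 32 of them called higher in Id1-/- (1.31% of the higher calls). Random scatter would put as many genes as far below, and 1 gene lay there; between the Id1+/+ libraries the numbers were 1 and 4. Of the 24 measured in AE9a, 5 were at least 2-fold higher in Id1-/- there (20.8%, 95% interval 7.13 to 42.2, against 14.2% of all genes measured, Fisher exact p = 0.373). That cut cannot decide on an effect of Id1 common to both models. All genes called higher in MLL-AF9 had a median AE9a log2 ratio of 0.74, which is under 2-fold. Y-linked transcripts had 0 counts in both Id1+/+ libraries and 108 and 17 in Id1-/- replicates 1 and 2, a scaled ratio of 6. Its 95% exact binomial interval, 3.58 to 10.7, covers counting error only. The median ratio was 3.59 over the 33 genes and 5.01 over the 6 of them with at most 5 Id1+/+ counts. RNA from a separate male cell source, more of it in Id1-/- replicate 1, is a candidate explanation; the sex of the animals was not used here, and which cells it came from was not tested.

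Matrix genes were higher in Id1-/- cultures in both models. A larger share of uniform stromal cells with unchanged expression per cell would raise genes made only by them by a common factor. The MLL-AF9 log2 folds of the matrix genes had an SD of 0.49 against a median SE of 0.09. The stromal genes Cxcl12 (-1.28) and Prrx1 (1.42) moved apart. This spread cannot exclude a larger share, since the SE covers replicate spread only and the cultures hold mixed cell types. Of 18 mesenchymal markers, 9 were higher and 2 lower in MLL-AF9, and 16 AE9a ratios were above 0 (median 1.73). The choice of TMM over library totals did not account for the rise of the matrix genes, with a median of 1.68 under library totals. Those totals shift the median of all genes by only 0.111 on the log2 scale, upward. Nor did whatever raised genes in Id1-/- replicate 1, with a median of 1.61 without that library. The log2 ratio of replicate 1 to 2 had a median of -0.12 over the matrix list. Some matrix genes are also made by other cells, and a larger stromal share, alone or joined with a change per cell, could still give these values. An effect of Id1 on matrix genes in these mixed cultures remains a hypothesis.

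Ifi202b was present in Id1-/- and nearly absent from Id1+/+ in both models, the 1 gene shared by the 6 in MLL-AF9 and the 40 in AE9a with at most 2 Id1+/+ counts and at least 20 in each Id1-/- library. Expression of this gene differs between inbred strains, so sequence from another strain carried with the knockout is a candidate explanation. Within 10 Mb of Id1, 38 of 162 genes were called (23.5% against 28% elsewhere, odds ratio 0.788, interval 0.532 to 1.14, Fisher exact p = 0.218). Within 1 Mb of Ifi202b, 7 of 13 were called (53.8% against 27.9%, odds ratio 3.01, interval 0.866 to 10.9, Fisher exact p = 0.0576). All 7 were lower, opposite to Ifi202b, and 6 of them are Ifi200 family genes, so these calls need not concern strain sequence; both intervals include 1, and strain sequence and an effect of Id1 on Ifi202b cannot be told apart here.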

How the results depend on the processing

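Library totals, the mean of both AE9a columns and the Id1 count implied by the other AE9a column were chosen as alternatives after the data were seen; the others were planned. Of 1438 MLL-AF9 log2 folds of 122 named genes under the alternatives, 1378 kept direction and side of the threshold, 47 lost a call, 5 gained one and 8 changed sign. Of 591 AE9a values for 118 ratios, 469 moved by less than the counting interval, 110 by more and 12 changed sign. Except where a stricter rule or fewer genes or libraries give it by construction, the cause was not tested.

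MLL-AF9 genes higher (2434) and lower (1502) in Id1-/- numbered 1085 and 68 with a 2-fold minimum, 3138 and 598 with library totals, and 1555 to 2234 and 621 to 1630 when 1 library was left out. The replicate block, which pairs replicates by number, gave 2956 and 2237, with 6 adipocyte genes lower and a camera adjusted p of 0.00729 for immediate early and heat shock genes. Gene lists past the threshold (14) numbered 0 with an estimated correlation. Genes with a different effect (1556) numbered 776 with DESeq2, 554 with a 2-fold minimum and 894 to 1763 leaving out 1 library. Genes higher in both models (1083) numbered 617 with DESeq2 and 596 with a 2-fold minimum; those lower in both (738) numbered 129 with library totals, 7 with a 2-fold minimum and 295 to 727 leaving out 1 library.

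AE9a genes at least 2-fold higher (1473) numbered 3659 with no filter and 811 with the mean of both columns; those lower (193) numbered 915 and 5473 in that order, 102 with library totals and 110 with the filter at 50 counts. The percent of MLL-AF9 higher genes with the same AE9a direction (80.9) was 82.6 with no filter, 78.8 with the filter at 50 counts, 83.2 with DESeq2, 77.8 with the replicate block, 87.8 with library totals, 77.9 with the mean of both columns and 77.8 to 88.8 leaving out 1 library. For lower genes (82.9) it was 85.8 with DESeq2, 80 with the block, 70.4 with library totals, 48.4 with the mean of both columns and 79 to 85.6 leaving out 1 library.

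In MLL-AF9, leaving out 1 library changed the sign of uncalled genes, with log2 folds of -0.96 to 0.24 for Ccl5, -0.52 to 1.01 for Lck, -0.58 to 1.08 for Cd4, -0.05 to 1.07 for Kdr and -0.36 to 0.05 for Lrch4. The mean of both AE9a columns adds a larger constant to Id1+/+ than to Id1-/-, which lowers the ratios of genes with few counts by construction, so those values say nothing on stability. With it the log2 ratio was -1.32 for Gfra2, -0.18 for U90926, -1.39 for Itga8, -0.81 for Angpt4, -0.41 for Cdkn2b, -0.57 for Ctsg, -0.06 for Ccl5, -0.71 for Lck, -0.93 for Egfl7 and -0.18 for Acta1, where it had been above 0. It rose to 0.13 for Id2 and 0.09 for Acp5, which have many counts, and there the cause was not tested. Planned and not run were tests, list tests and left-out libraries for AE9a alone, a blocked joint fit, the fit of 8 libraries, and alternatives for normalized values or the authors' adjusted p.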

Other observations

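The gene families and genes in this part were chosen after the data were seen, and no explanation was tested for them.

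Of 38 immunoglobulin genes tested in MLL-AF9, 29 were higher and 0 lower in Id1-/- by edgeR (median log2 2.21), 32 and 0 with library totals and 19 and 0 without Id1-/- replicate 1. Ighg1 went from 3.82 ± 0.342 to 37.6 ± 2.73 CPM. Of 13 cathepsins, 10 were lower and 2 higher (median -0.32), 7 and 2 with library totals and 6 and 1 without Id1-/- replicate 1, and the AE9a median was -0.53. Ctsl had a log2 fold of -0.68 and Ctsd of -0.48. Of 83 ribosomal protein genes 2 were higher and 2 lower, and 4 and 0 with library totals, where the median turned from -0.05 to 0.06.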
